A study of Rattus norvegicus with 9 samples.

How the data were processed

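Kidney RNA was measured in 9 male rats of 3 inbred strains, 3 animals each: the Dahl salt-sensitive strain (Dahl S), the Dahl salt-resistant strain (Dahl R) and the spontaneously hypertensive rat (SHR). Per the labels, the rats were weaned at 30 days, then kept on a diet with 0.3% salt, and were 53 days old. Labelled Cy3 targets made from 1 μg of RNA were put on a one-colour array with probes for coding and long noncoding transcripts, 1 array per animal. The labels do not say whether animals shared a litter or a preparation day, so the p-values measure the spread between samples.

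The authors deposited the scanner output of each array, made with Agilent Feature Extraction 10.5.1.1. Per the file headers, the processed signal is an intensity that the software had background-subtracted, detrended across the array and raised to a floor, with no normalization between arrays. The deposited median signal of each spot and of its local background is an intensity with no correction. Other deposited columns mark whether a spot was well above background, saturated, or an outlier by uneven pixels or by disagreement with its replicate spots. The authors also deposited a table of processed values for 19407 probes. Its scale, normalization and filter are not stated. Against the scanner signals of the same array on a log2 scale, its columns correlated with r of 0.974 for SHR replicate 3 and 0.999 to 1.00 for the other 8 arrays, so the authors' values were read as log2. The column medians were 9.63377 on 7 arrays, 9.63 on SHR replicate 2 and 9.64 on SHR replicate 3, and the quartiles nearly coincided except for the lower quartile of SHR replicate 3. How these values were normalized stays unknown, and they were used only as an alternative.

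Each array held 43553 spots, of which 1417 were controls and were left out. The remaining 42136 spots carried 24684 probes. The class of a probe was read from its name, since no column states it: 15365 were taken as coding and 9319 as noncoding. Through their RefSeq identifiers, 14274 coding and 20 noncoding probes were matched to a current symbol, for 13903 genes; 1091 coding probes kept the name in the file. No genome coordinates are given, because the array grid and the reference table use different genome builds. Neither do the files hold probe sequences. The probes follow a reference rat sequence, so a sequence difference between strains under a probe can change its signal, and this was not testable.

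The processed signal was put on the log2 scale, and the log2 of each array's 75th percentile over all its non-control spots was subtracted. Spots marked as outliers were then set to missing, and the spots of a probe were averaged. No spot was saturated on any array (0 spots). A probe was tested if at least 0.5 of its spots were well above background on at least 3 arrays and each strain kept a usable spot. This left 16592 probes, 11942 coding and 4650 noncoding, for 10861 genes; 26 probes passed the signal filter but lacked a usable spot in a strain. For the 254 genes with several tested probes, the probe with the highest mean over the 9 arrays stood for the gene.

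The version of the values coded first took the percentile over probe means of spots without an outlier mark, and judged detection on those spots. It gave 38, 601 and 477 probes past the threshold for Dahl S against Dahl R, Dahl S against SHR and SHR against Dahl R, and 742, 4205 and 3482 without SHR replicate 3. These counts were seen before it was replaced. The reason for replacing it was SHR replicate 3. Of the spots in the brightest 10% on SHR replicate 1, 48.2% are marked as outliers on SHR replicate 3. The 75th percentile of SHR replicate 3 was 710 over spots without a mark and 1462 over all spots. The percentile in the header of that file is 1462, and the written design names the array's percentile without excluding spots. Both versions are given wherever their counts are compared.

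Differences between strains were tested with limma 3.58.1 (lmFit, contrasts.fit and eBayes) in R 4.3.3, with strain as the only term and all 9 arrays sharing 1 estimate of the spread per probe. P-values were adjusted by Benjamini-Hochberg over all tested probes within each comparison, at a threshold of 0.05. Differences are given as the mean log2 difference ± its standard error (SE), and levels as mean log2 signal relative to the array's 75th percentile ± standard deviation (SD). Where a probe was well above background on no array of a strain, the fold is a bound, written as at least. It sets the mean of the brighter strain against the mean, per array of the dimmer strain, of the higher of the probe's own signal and the lowest signal among probes well above background. A probe well above background on only 1 of the 3 arrays of a strain is given as a log2 difference without a fold. With 2 such arrays the fold of the means is given with their number for the largest changes, and is less certain. Genes were ranked by the fitted difference, so the rank of a probe given as a bound or without a fold rests partly on signals not well above background. The number of arrays, 3 per strain, limits the precision. Overlaps between comparisons that share arrays were set beside 50 simulations with no effect and beside the overlap of independent lists.

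The test, threshold, alternatives, gene lists and the rule for naming genes were chosen before the data were examined, except where stated otherwise. The 30 lists hold 897 genes, 872 with a current symbol, and cover pathways of blood pressure control, metabolism, immunity and stress, and markers of the cell types a kidney sample could hold. Each list with at least 5 measured members was tested with limma's camera at a preset inter-gene correlation of 0.01 on 1 probe per gene, adjusted over the 29 lists that qualified. Camera with an estimated correlation and fry were run beside it. The rule draws the named genes, per comparison, from the 10 largest rises and 10 largest falls among coding probes past the threshold whose 2 groups did not overlap, and 5 and 5 among noncoding probes. It adds up to 2 risen and 2 fallen members of each list, and the measured members of the lists for the renin-angiotensin system, renal sodium transport and rat hypertension candidates.

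Array slides, read from the headers, were used as a batch: slide 1 held the 3 Dahl S arrays and Dahl R replicate 1, slide 2 held Dahl R replicates 2 and 3 with SHR replicates 1 and 2, and slide 3 held SHR replicate 3 alone. With slide as a block, SHR replicate 3 therefore adds nothing to the differences between strains. The difference between Dahl S and Dahl R then sets the 3 Dahl S arrays against Dahl R replicate 1 alone. Dahl S and SHR share no slide. Alternatives were quantile normalization, median centring, normexp background correction with an offset of 50, other filters on dim probes, outlier spots kept, a slide block, a replicate block, fits of only the 2 strains compared, an intensity trend with a robust prior, array weights, a minimum of 2-fold, the authors' value table, the mean of a gene's probes, and each array left out in turn. Normexp was run on the median signal, because the files hold no mean signal. The version coded first and the percentile over spots without an outlier mark were added to the alternatives when the main scaling was replaced, after the data were seen.

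The procedure was tested on simulated data with 200 changed probes among 16592. For Dahl S against Dahl R it recovered 47.8% of 2-fold, 95.5% of 4-fold and 92.4% of 8-fold changes, with 10 unchanged probes called. For Dahl S against SHR the shares were 49.3%, 85.1% and 97.0%, with 6 unchanged probes called, and for SHR against Dahl R 49.3%, 74.6% and 89.4%, with 9. For the list test the members of 3 lists were each moved by 1 (log2) in Dahl S. All 3 lists were recovered in each of the first 2 comparisons, with 1 other list called in each. None were shifted for SHR against Dahl R and 0 were called. The simulated noise held no correlation between genes and no array noisier than the others, so these rates need not hold in the real data. Python 3.11.15 and matplotlib 3.10.9 drew the plots.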

Results

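Expression of coding and long noncoding transcripts was measured in kidneys of young male Dahl S, Dahl R and SHR rats on a low-salt diet, with 3 arrays per strain. Dahl S rats become hypertensive when fed salt, Dahl R rats were bred from the same stock to resist this, and SHR become hypertensive without added salt. In 8 of the 9 arrays, between 60.1% and 70.3% of probes were well above background, and log2 signals correlated with r of 0.951 to 0.997 across probes, which are not independent replicates. Dahl S replicate 1 gave the lowest of these, with r of 0.974 and 0.973 to the other Dahl S arrays, which correlated with each other at 0.996; its share of outlier spots, 2.62%, was the highest of the 8. SHR replicate 3 stood further apart. There 43.1% of probes were well above background, the median local background was 88 against 43 to 45 on the other arrays, and r with other arrays was 0.920 to 0.956. The 75th percentile of the signal was 1462 on that array and 2120 to 2751 on the others. Counts of probes are therefore given with and without it, and other values with it unless stated.

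The comparison of Dahl S with Dahl R asks how kidneys of the salt-sensitive and salt-resistant lines differ before a salt load. Xdh, which makes uric acid from purines, was at least 53.7-fold higher in Dahl S (log2 difference 7.11 ± 0.22, SE, n = 3 and 3, adjusted p = 1.15e-05) and was not well above background on any Dahl R array. Asb3 was 36.7-fold higher (5.20 ± 0.11, adjusted p = 1.15e-06) and Resp18, a protein of the secretory pathway, 21.5-fold higher (4.43 ± 0.19, adjusted p = 6.06e-05). Havcr1, known as kidney injury molecule, was 9.84-fold higher (3.30 ± 0.30, adjusted p = 0.00193), at 1.33 ± 0.62 (SD) in Dahl S and -1.97 ± 0.30 in Dahl R. Lower in Dahl S were Hsd3b2, a steroid-synthesis enzyme (-5.04 ± 0.38, adjusted p = 0.000892, with a bound of -3.39, as no Dahl S array was well above background), Cyp2c11, an androgen-dependent enzyme that oxidises steroids and arachidonic acid (24.1-fold, -4.59 ± 0.57, adjusted p = 0.00966), and Mx2, an interferon-induced gene (8.14-fold, -3.03 ± 0.17, adjusted p = 0.000167).

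The other largest rises in Dahl S were Akr1b7 (at least 59.3-fold), Prkg2 (at least 10.6-fold), Clca1 (at least 6.33-fold), Galnt13 (15.6-fold), Cd209a (log2 difference 3.90) and Ly6i (12.9-fold). By fitted difference, the other largest falls were Tmem209 (9.07-fold), Mlc1 (6.90-fold), Ly6al (6.44-fold), Cdc42ep1 (5.78-fold), Siglec5 (5.40-fold), Tacr3 (log2 difference -2.35) and Mybphl (at least 2.53-fold, a bound that would not place it among them), with adjusted p from 7.26e-05 to 0.0483 over these 13 genes. Cd209a was well above background on 1 of 3 Dahl R arrays, Tacr3 on 1 of 3 Dahl S arrays, and Tmem209 and Siglec5 on 2 of 3 Dahl S arrays. Under normexp background correction the differences of Tacr3 and Mybphl turned to 0.16 and 0.78. Among noncoding probes, named here as in the files, MRAK038897 (at least 40.2-fold), MRFT35653 (at least 19.5-fold), XR_007868 (11.9-fold), XR_008415 (10.7-fold) and XR_005427 (7.37-fold) were highest over Dahl R. XR_007075 (log2 difference -5.03), MRAK161905 (9.07-fold), XR_008045 (8.62-fold), MRAK044962 (7.64-fold) and uc.95- (at least 2.18-fold, turned to 0.72 under normexp) were lowest. XR_007075 was well above background on 1 and XR_008045 on 2 of 3 Dahl S arrays, and XR_005427 on 2 of 3 Dahl R arrays.

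Gene lists that shifted upward in Dahl S included kidney injury genes: 4 of 31 measured members rose, 0 fell and 27 did not pass (median log2 difference 0.31, camera adjusted p = 1.99e-06, and 0.464 with an estimated correlation). Adjusted over the list alone, 8 rose and 2 fell. Besides Havcr1, its members included Fgg, a fibrinogen chain, 3.55-fold higher (1.83 ± 0.20, adjusted p = 0.00503). Blood cell genes had a median of 0.97 (adjusted p = 1.99e-06, and 0.140 with an estimated correlation); 1 of 9 passed over all probes and 6 rose adjusted over the list alone. The 1 gene, the anion exchanger Slc4a1 (1.72-fold, 0.78 ± 0.13, adjusted p = 0.0483), is a marker of both red cells and collecting duct. Collecting duct genes had a median of 0.23 (1 of 20 rose, 3 adjusted over the list alone, adjusted p = 0.00457, and 0.704 with an estimated correlation).

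Fibrosis genes had a median of 0.24 in Dahl S over Dahl R, with 2 of 30 higher, 0 lower and 28 not passing (2 and 1 adjusted over the list alone, camera adjusted p = 0.00233, and 0.683 with an estimated correlation). The matrix proteoglycan Dcn was 3.63-fold higher (1.86 ± 0.27, adjusted p = 0.0199). Immediate early and heat shock genes had a median of 0.37, with 0 of 25 past the threshold over all probes and 7 higher adjusted over the list alone (adjusted p = 1.33e-05, and 0.464 with an estimated correlation). Proliferation genes had a median of 0.32 with 0 of 21 past the threshold by either adjustment (adjusted p = 0.00339, and 0.683 with an estimated correlation). Blocking for slide leaves only Dahl R replicate 1 to set against the 3 Dahl S arrays, so values with that block are no separate support. With slide as a block, the camera adjusted p was 0.000148 for kidney injury, 2.2e-05 for blood, 6.72e-06 for collecting duct, 0.324 for fibrosis, 0.00265 for immediate early genes and 0.00265 for proliferation. Within slide 1 these were 0.00042, 3.53e-05, 3.35e-06, 0.213, 0.0017 and 3.53e-05, but there 1 Dahl R array stands against 3 Dahl S arrays that alone supply the spread, and all 4 also made the calls, so these values are no separate support. The fibrosis median was 0.13 and that of collecting duct 0.39 with slide as a block. Under normexp, proliferation and immediate early genes had an adjusted p of 0.0605, fibrosis 0.306 and collecting duct 0.324. Collecting duct also had 0.12 without Dahl S replicate 3 and 0.131 without Dahl R replicate 1. The remaining 23 lists gave adjusted p from 0.089 to 0.907. With slide as a block, fat (0.0198, lower), interferon response (0.0488, higher) and proximal tubule (0.0488, lower) also passed. With an estimated correlation and no block, their camera adjusted p was 0.709, 0.683 and 0.709.

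Of the renin-angiotensin genes, Prcp, which degrades angiotensin peptides, was 3.94-fold lower in Dahl S (-1.98 ± 0.29, adjusted p = 0.0199), and the other 14 of 15 did not pass. Agt differed by 0.01 ± 0.17, Agtr1a by 0.02 ± 0.20 and Anpep by 0.73 ± 0.13 (adjusted p = 0.0518). Among 35 sodium and electrolyte transport genes, Slc4a1 rose and 34 did not pass: Slc12a3, the thiazide-sensitive cotransporter, differed by -0.09 ± 0.25, Scnn1b by -0.13 ± 0.20, and Sgk1, the aldosterone-induced kinase, by 0.77 ± 0.14 (adjusted p = 0.0549). Of 32 measured rat hypertension candidates, Resp18 and Gstm1 (1.95-fold, 0.96 ± 0.17, adjusted p = 0.0437) rose and 30 did not pass, among them Ephx2 at 0.06 ± 0.11 and Cd36 at 0.00 ± 0.22. Clock genes moved both ways: Nfil3 was 2.77-fold higher (adjusted p = 0.00434) and Dbp 2.38-fold lower (adjusted p = 0.0157), while 13 of 15 did not pass.

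In all, 233 of 16592 probes differed between Dahl S and Dahl R, 117 higher and 116 lower in Dahl S (50.2% higher, and 65.1% of 43 under normexp), of which 192 were coding and 41 noncoding; 153 differed at least 2-fold. The values of each strain did not overlap in 31.1% of probes, against 10% by chance with 3 usable arrays per strain and more where values are missing. Without SHR replicate 3, which enters through the shared spread, 761 probes passed, including all 233; 38 passed in the version coded first, 35 of them shared. With slide as a block, where Dahl R counts through replicate 1 alone, 164 passed. Within slide 1, where Dahl R has only that 1 array, all 233 had the same direction. These arrays also made the calls. Of the 46 named genes past the threshold, 18 passed in the version coded first, 46 without SHR replicate 3 and 27 with slide as a block, where the differences stayed similar but the adjusted p was 0.0544 for Havcr1 (3.08), 0.0615 for Cyp2c11 (-4.52), 0.234 for Akr1b7 (6.74) and 0.314 for Mybphl (-2.42). Leaving out Dahl S replicates 1, 2 and 3 kept 29, 22 and 23 of these 46 named genes. Leaving out the Dahl R replicates in the same order kept 23, 22 and 24. The count of probes was 125, 78 and 80 without Dahl S replicates 1, 2 and 3, and 88, 74 and 85 without Dahl R replicates 1, 2 and 3.

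The comparison of Dahl S with SHR sets side by side 2 separately derived strains. Both are called hypertensive here by strain, and not by a measured blood pressure. RT1-Bb, a class II histocompatibility chain, was higher in Dahl S (10.08 ± 0.82, adjusted p = 0.000243), at 4.63 ± 0.11 (SD, n = 3) against -5.46 ± 1.95 in SHR, where 1 of 3 arrays was well above background. Dio1, which activates thyroid hormone, was 74.1-fold higher (6.21 ± 0.38, adjusted p = 6.88e-05), and the phosphate and urate transporter Slc17a3 21.6-fold higher (4.43 ± 0.18, adjusted p = 9.74e-06). Higher in SHR were Ifit1, an interferon-induced gene (at least 67.1-fold, -7.14 ± 0.30, adjusted p = 1.12e-05), Nr1h4, the bile acid receptor (41.9-fold, -5.39 ± 0.26, adjusted p = 2.01e-05), and Areg, a ligand of the epidermal growth factor receptor (31.6-fold, -4.98 ± 0.22, adjusted p = 1.35e-05). Ephx2, which breaks down epoxides of arachidonic acid, was 14.9-fold higher in SHR (-3.90 ± 0.12, 2 usable SHR arrays, adjusted p = 9.74e-06).

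Other large differences toward Dahl S were Hba-a3 (at least 280-fold), Zfp37 (at least 126-fold), Ubd (46.4-fold), Psmd8 (42.1-fold), Or2n1e (40.8-fold), Galnt13 (log2 difference 4.80), Bcl9l (23.4-fold) and Akr1b7 (log2 difference 4.52). Toward SHR they were Dtx3l (76.1-fold), Cyp8b1, a bile acid synthesis enzyme (52.3-fold, 2 usable SHR arrays), Stbd1 (39.0-fold), Ugt2a1 (at least 16.9-fold), Coro2a (at least 8.02-fold) and Ccl11 (at least 4.54-fold), the last 2 well above background on 2 SHR arrays. Adjusted p lay between 5.18e-07 and 0.0375 over these 14 genes; Akr1b7 had the highest, and 0.136 in the version coded first. Galnt13 and Akr1b7 were well above background on 1 of 3 SHR arrays, and Ubd, Psmd8 and Or2n1e on 2 of 3. A sequence difference between strains under a probe could also change such signals, here and in the other comparisons, and was not testable. The largest noncoding differences were X83579 (at least 36.1-fold), MRAK134201 (at least 32.4-fold), BC105611 (at least 45.3-fold), MRuc008qku (45.1-fold) and MRAK050663 (at least 12.7-fold) toward Dahl S. Toward SHR they were U65217 (at least 521-fold) and XR_007560 (36.5-fold), each on 2 usable SHR arrays, BC091362 (log2 difference -5.15), BC091258 (31.8-fold) and BC088860 (at least 15.6-fold). MRAK050663 had an adjusted p of 0.0134, and 0.093 in the version coded first. MRuc008qku was well above background on 2 of 3 SHR arrays and BC091362 on 1 of 3 Dahl S arrays.

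Kidney injury genes were higher in Dahl S than in SHR: 13 of 31 higher, 3 lower and 15 not passing (15 and 3 adjusted over the list alone, median 0.52, camera adjusted p = 2.41e-05, and 0.538 with an estimated correlation). Havcr1 was 21.8-fold higher (4.45 ± 0.30, adjusted p = 0.000105, well above background on 2 of 3 SHR arrays), the cell-cycle inhibitor Cdkn1a 2.71-fold higher (1.44 ± 0.20, adjusted p = 0.00294) and the keratin Krt19 1.90-fold lower (-0.92 ± 0.17, adjusted p = 0.0114). Leukocyte genes were higher in 7 of 28, lower in 0 and not passing in 21 (7 and 0 adjusted over the list alone, median 0.30, adjusted p = 0.000989, and 0.538 with an estimated correlation). Among them the macrophage receptor Mrc1 was 2.44-fold higher (1.29 ± 0.15, adjusted p = 0.0013) and Cx3cr1 1.74-fold higher (0.80 ± 0.10, adjusted p = 0.00226, well above background on 2 of 3 SHR arrays). Of the fibrosis genes 7 of 30 were higher, 2 lower and 21 not passing (8 and 2 adjusted over the list alone, median 0.30, adjusted p = 0.003, and 0.724 with an estimated correlation), with Loxl2 5.71-fold higher (well above background on 2 of 3 SHR arrays) and Mmp9 2.52-fold lower on 2 usable Dahl S arrays. Genes of oxidant production and antioxidant defence, a list that mixes both, were higher in 10 of 47, lower in 3 and not passing in 34 (14 and 5 adjusted over the list alone, median 0.18, adjusted p = 0.0179, and 0.538 with an estimated correlation). The glutathione enzymes Gstt2 and Gpx2 were 3.15-fold and 2.66-fold higher (Gpx2 well above background on 2 of 3 SHR arrays), and catalase, Cat, 1.35-fold lower.

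Proximal tubule markers were higher in Dahl S than in SHR in 5 of 21 cases, with 0 lower and 16 not passing (6 and 0 adjusted over the list alone, median 0.28, camera adjusted p = 0.000989, and 0.538 with an estimated correlation). Collecting duct markers were lower in 10 of 20, higher in 0 and not passing in 10 (12 lower adjusted over the list alone, median -0.60, adjusted p = 0.00476, and 0.724 with an estimated correlation). Scnn1b, a chain of the epithelial sodium channel, was 3.06-fold lower (-1.62 ± 0.20, adjusted p = 0.00185) and the water channel Aqp4 2.79-fold lower (-1.48 ± 0.25, 2 usable SHR arrays, adjusted p = 0.0103). Fat cell genes were lower in 3 of 11, higher in 0 and not passing in 8 (5 lower adjusted over the list alone, median -0.77, adjusted p = 0.0163, and 0.724 with an estimated correlation), among them Ucp1 at 3.97-fold and Lpl at 3.22-fold, each on 2 usable SHR arrays. Ribosomal protein genes had a median of 0.10, with Rpl19 higher on 2 usable SHR arrays and 51 of 52 not passing (0 adjusted over the list alone, adjusted p = 0.00954, and 0.724 with an estimated correlation); under normexp this shift turned downward.

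With slide as a block, the camera adjusted p for Dahl S against SHR was 0.0036 for kidney injury, 0.0281 for leukocytes, 0.00484 for fat, 0.237 for fibrosis, 0.195 for oxidant and antioxidant genes, 0.102 for proximal tubule, 0.151 for collecting duct and 0.268 for ribosomal proteins. The median then shrank to 0.05 for proximal tubule, -0.26 for collecting duct, 0.12 for fibrosis and 0.04 for ribosomal proteins, while oxidant and antioxidant genes stayed at 0.14. Under normexp it was 0.0788 for fibrosis, 0.317 for oxidant and antioxidant genes, 0.105 for proximal tubule and 0.36, in the other direction, for ribosomal proteins. With the authors' values it was 0.15 for oxidant and antioxidant genes, 0.15 for proximal tubule and 0.405 for ribosomal proteins, which had 0.193 with quantile normalization. Oxidant and antioxidant genes had an adjusted p of 0.0702 and a median of 0.11 without SHR replicate 3, collecting duct 0.0636 without SHR replicate 1, and fat 0.145 without SHR replicate 2. Ribosomal proteins had 0.0568 without Dahl S replicate 3 and 0.084 without SHR replicate 2. The remaining 21 lists gave adjusted p from 0.0605 to 0.942. With slide as a block, endothelium passed as lower in Dahl S (0.0281, against 0.241). Its camera adjusted p was 0.724 with an estimated correlation and no block.

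Agt, the angiotensin precursor, was 2.64-fold higher in Dahl S than in SHR (1.40 ± 0.17, adjusted p = 0.00185), and the mast cell protease Cma1 4.95-fold lower (-2.31 ± 0.33, adjusted p = 0.00359). Prcp (1.15 ± 0.29), Nln (0.42 ± 0.11), Mas1 (-1.09 ± 0.26) and Nr3c2 (-0.38 ± 0.09) also passed, and 9 of 15 renin-angiotensin genes did not. Of the transport genes 4 of 35 were higher in Dahl S, 7 lower and 24 not passing. The bicarbonate cotransporter Slc4a4 was 8.84-fold higher (3.14 ± 0.42, adjusted p = 0.00252) and Sgk1 2.11-fold higher (1.08 ± 0.15, 2 usable SHR arrays, adjusted p = 0.00545). Among hypertension candidates 7 of 32 were higher, 3 lower and 22 not passing. The fatty acid transporter Cd36 was 5.51-fold higher (2.46 ± 0.22, adjusted p = 0.000375), Sorcs2 3.95-fold (1.98 ± 0.14, adjusted p = 0.000132) and Nr2f2 3.63-fold (1.86 ± 0.26, adjusted p = 0.00344).

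Between Dahl S and SHR 2605 probes differed, 1174 higher and 1431 lower in Dahl S (45.1% higher, against 55.2% with quantile normalization, 70.4% under normexp and 61.3% with slide as a block), with 1881 coding and 724 noncoding; 1157 differed at least 2-fold. The strains did not overlap in 37.9% of probes, against 10% by chance where all arrays are usable and more where values are missing. Without SHR replicate 3, 4345 passed, 2519 of them shared; 601 passed in the version coded first, 552 of them shared, and 866 with slide as a block, which rests on the slides being linked through Dahl R. Of the 128 named genes past the threshold, 64 passed in the version coded first, 127 without SHR replicate 3 and 61 with slide as a block. Leaving out Dahl S replicates 1, 2 and 3 kept 97, 83 and 96 of them, and leaving out SHR replicates 1 and 2 kept 113 and 102. The median over all tested probes was -0.09 for Dahl S against SHR, 0.11 for SHR against Dahl R and 0.02 for Dahl S against Dahl R, and list medians are given without subtracting it. Other scalings of the scanner signals moved it to between -0.42 and 0.11, 0.18 and 0.42, and 0.00 and 0.14, in that order. The count of probes was 1280 and 1510 without Dahl S replicates 2 and 3.

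The comparison of SHR with Dahl R sets the other hypertensive strain against the salt-resistant line. Ifit1 was at least 112-fold higher in SHR (7.17 ± 0.30, n = 3 and 3, adjusted p = 1.01e-05), Nr1h4 70.8-fold (6.15 ± 0.26, adjusted p = 1.01e-05) and Xdh at least 22-fold (5.82 ± 0.22, adjusted p = 5.39e-06). Ephx2 was 15.6-fold higher (3.96 ± 0.12, 2 usable SHR arrays, adjusted p = 9.55e-06), and Cyp2j4, an enzyme that makes the epoxides Ephx2 breaks down, 5.22-fold higher (2.38 ± 0.24, adjusted p = 0.000764). RT1-Bb was lower in SHR (-9.83 ± 0.82, adjusted p = 0.000327, well above background on 1 of 3 SHR arrays), Dio1 84.2-fold lower (-6.40 ± 0.38, adjusted p = 6.19e-05), Slc17a3 23.5-fold lower (-4.55 ± 0.18, adjusted p = 8.97e-06), and Il33, a cytokine of injured epithelium, 20.5-fold lower (-4.36 ± 0.16, 2 usable SHR arrays, adjusted p = 1.87e-05).

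Other large rises in SHR were Dtx3l (87.6-fold), Stbd1 (45.2-fold), Asb3 (37.1-fold), Cyp8b1 (35.6-fold, 2 usable SHR arrays), Ugt2a1 (log2 difference 4.14) and Clca1 (at least 6.07-fold). The other largest falls were Hba-a3 (at least 193-fold), Zfp37 (at least 104-fold), Or2n1e (38.2-fold), Psmd8 (35.4-fold), Ubd (22.2-fold) and Cst7 (at least 13.7-fold). Adjusted p ranged from 3.43e-07 to 0.0129 over these 12 genes; that of Cst7 was the highest, and 0.0899 in the version coded first. Ugt2a1 was well above background on 1 of 3 Dahl R arrays, and Clca1, Or2n1e, Psmd8 and Ubd on 2 of 3 SHR arrays. Noncoding probes higher in SHR were U65217 (at least 824-fold) and XR_007560 (41.0-fold), each on 2 usable SHR arrays, MRAK038897 (at least 34.2-fold), MRFT35653 (at least 12.0-fold) and BC088860 (at least 24.2-fold). Those lower were X83579 (at least 33.9-fold), MRAK134201 (at least 32.4-fold), BC105611 (at least 46.0-fold), MRuc008qku (42.2-fold) and MRAK050663 (at least 12.8-fold). MRAK050663 had an adjusted p of 0.0155, and 0.103 in the version coded first. MRFT35653 and MRuc008qku were well above background on 2 of 3 SHR arrays.

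**Figure D1:**
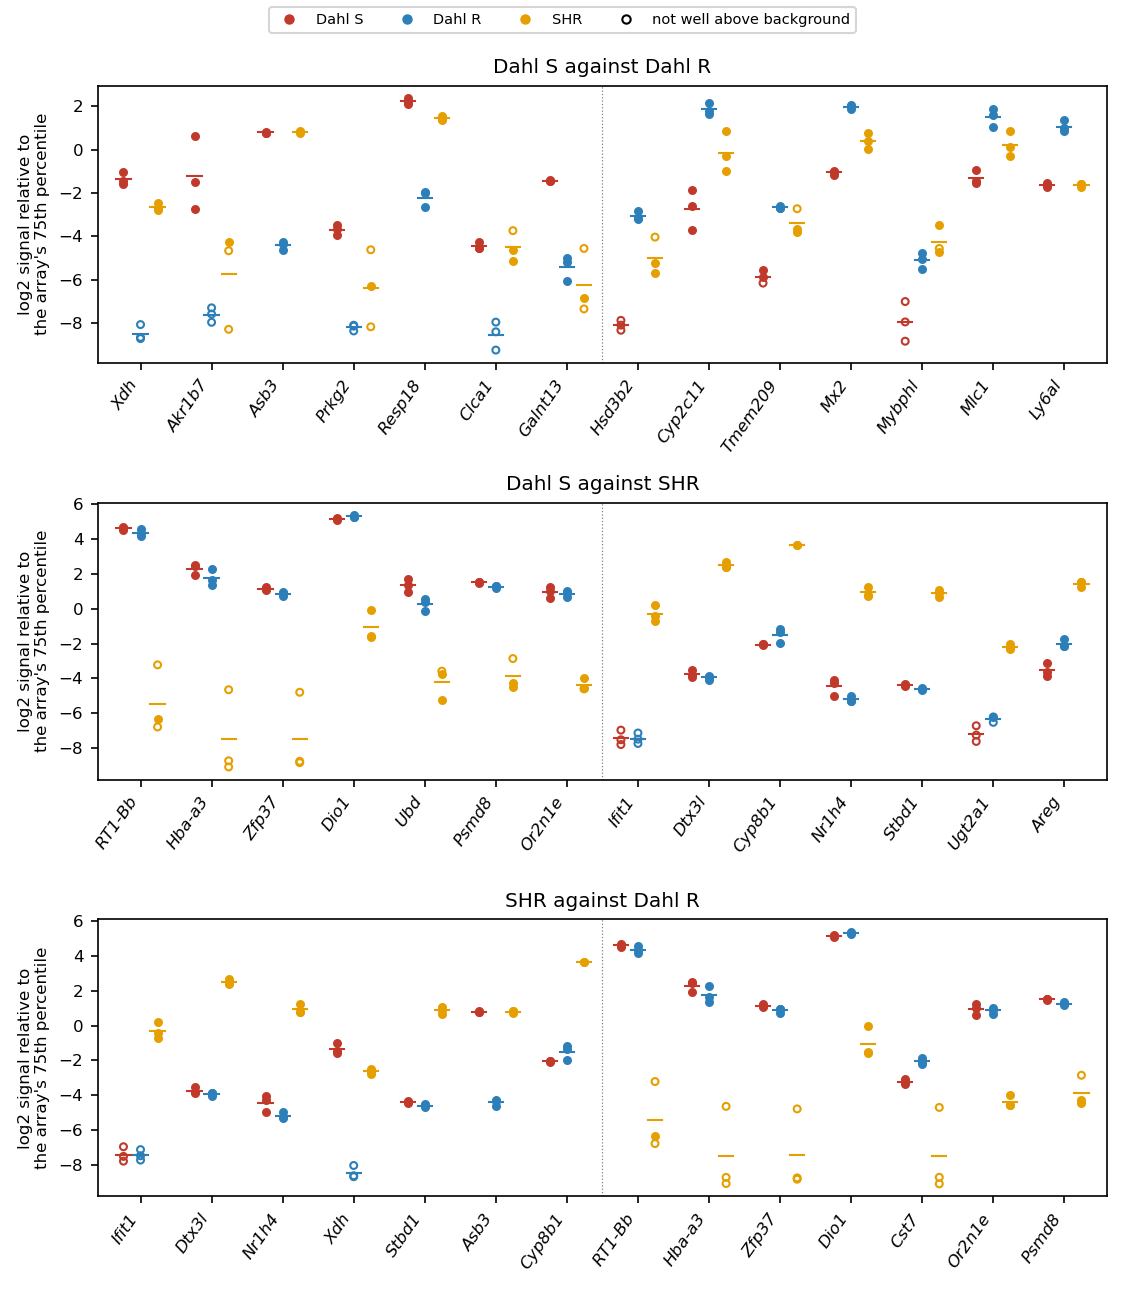
Log2 signal of the 14 coding genes with the largest changes in each comparison, 7 up and 7 down, relative to the array's 75th percentile, for each array (points), with the strain mean as a dash; open symbols were not well above background. The RT1-Bb signals of Dahl S and Dahl R lie far above those of SHR, and Xdh is an open symbol on every Dahl R array.

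Collecting duct markers were higher in SHR than in Dahl R in 13 of 20 cases, with 0 lower and 7 not passing (14 higher adjusted over the list alone, median 0.73, camera adjusted p = 5.68e-06, and 0.535 with an estimated correlation). Scnn1b was 2.81-fold higher (1.49 ± 0.20, adjusted p = 0.00303) and the ammonia transporter Rhbg 2.71-fold higher (1.44 ± 0.16, adjusted p = 0.00134). Proximal tubule markers were lower in 6 of 21, higher in 0 and not passing in 15 (7 lower adjusted over the list alone, median -0.34, adjusted p = 1.29e-05, and 0.486 with an estimated correlation). Besides Slc17a3, Glyatl2 was 4.06-fold lower (-2.02 ± 0.45, 2 usable SHR arrays, adjusted p = 0.031). Leukocyte genes were lower in 4 of 28, higher in 1 and not passing in 23 (4 and 1 adjusted over the list alone, median -0.33, adjusted p = 0.000436, and 0.527 with an estimated correlation): Mrc1 was 1.89-fold lower and Itgam, an integrin chain of myeloid cells, 2.12-fold higher (well above background on 2 of 3 arrays of each strain). Of the oxidant and antioxidant genes 7 of 47 were lower, 2 higher and 38 not passing (7 and 2 adjusted over the list alone, median -0.20, adjusted p = 0.000454, and 0.486 with an estimated correlation), with Gstt2 3.72-fold lower and Gstm2 1.95-fold higher. With slide as a block, the adjusted p was 9.65e-06 for collecting duct, 0.000608 for proximal tubule, 0.00366 for leukocytes and 0.0121 for oxidant and antioxidant genes, and within slide 2 0.000134, 0.000518, 0.00349 and 0.0117. Both sets of values rest on the same difference, SHR replicates 1 and 2 against Dahl R replicates 2 and 3. Those arrays also made the calls, so neither set is separate support. The other 25 lists gave adjusted p from 0.0894 to 0.985. With slide as a block, endothelium passed as higher in SHR (0.0449, against 0.1). Its camera adjusted p was 0.0776 within slide 2, and 0.894 with an estimated correlation and no block. Groupings of the same arrays that mix the strains gave up to 8, 9 and 8 shifted lists in the 3 comparisons in turn, so the number of shifted lists does not set the strains apart.

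**Figure D2:**
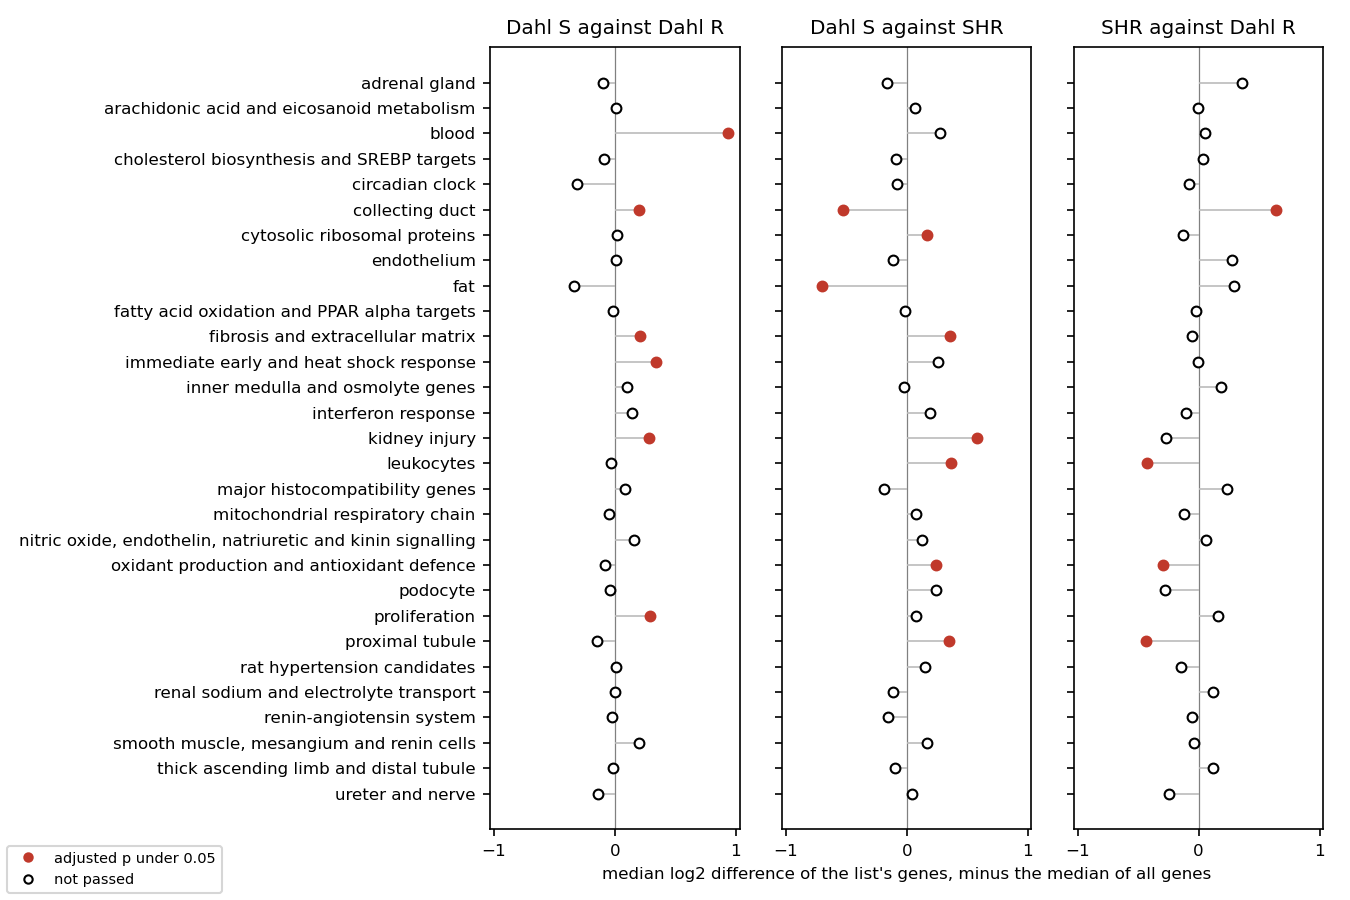
Median log2 difference of each of 29 gene lists minus the median of all genes, in the 3 comparisons; filled points had a camera adjusted p under 0.05 at the preset correlation. Filled points number 6 for Dahl S against Dahl R, 8 for Dahl S against SHR and 4 for SHR against Dahl R, and 0 in each with an estimated correlation.

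Prcp was 8.72-fold lower in SHR than in Dahl R (-3.12 ± 0.29, adjusted p = 0.000559) and Agt 2.63-fold lower (-1.40 ± 0.17, adjusted p = 0.00217). Anpep, an aminopeptidase that trims angiotensin, was 1.90-fold higher (0.93 ± 0.14, 2 usable SHR arrays, adjusted p = 0.00775). In all 4 of 15 renin-angiotensin genes were higher and 3 lower. Of 35 transport genes 6 were higher, 3 lower and 26 not passing. Slc4a4 was 5.96-fold lower (-2.58 ± 0.42, adjusted p = 0.00717) and the anion exchanger Slc26a4 2.04-fold higher (1.03 ± 0.18, 2 usable SHR arrays, adjusted p = 0.0125). The kinase Wnk4 differed by -0.02 ± 0.39 and, without SHR replicate 3, by 0.50 (adjusted p = 0.0397). Among hypertension candidates 3 of 32 were higher, 3 lower and 26 not passing, with Resp18 12.6-fold higher (3.66 ± 0.19, adjusted p = 3.15e-05), Cd36 5.50-fold lower (-2.46 ± 0.22, adjusted p = 0.000459) and Sorcs2 3.78-fold lower (-1.92 ± 0.14, adjusted p = 0.00018).

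Between SHR and Dahl R 2165 probes differed, 1254 higher and 911 lower in SHR (57.9% higher, and 41.1% under normexp), with 1613 coding and 552 noncoding; 912 differed at least 2-fold. The strains did not overlap in 38.8% of probes, against 10% by chance where all arrays are usable and more where values are missing. Without SHR replicate 3, 3772 passed, 2092 of them shared; 477 passed in the version coded first, 429 of them shared, and 2648 with slide as a block. Within slide 2, on which these calls partly rest, all 2152 called probes with a value had the same direction, and 2071 probes passed. Of the 113 named genes past the threshold, 56 passed in the version coded first, 109 without SHR replicate 3 and 99 with slide as a block. Leaving out Dahl R replicates 1, 2 and 3 kept 74, 72 and 79 of these 113, and leaving out SHR replicates 1 and 2 kept 99 and 87. The count of probes was 1034, 960 and 1157 without Dahl R replicates 1, 2 and 3.

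**Figure D3:**
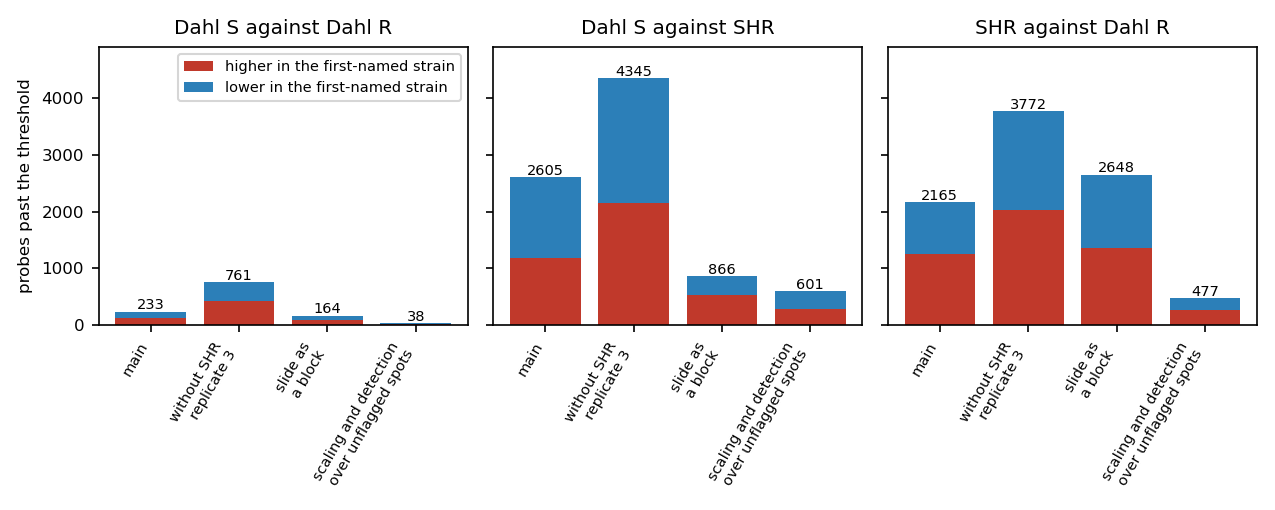
Number of probes past an adjusted p of 0.05 in each comparison, stacked as higher and lower in the strain named first, for all arrays, without SHR replicate 3, with slide as a block and with scaling and detection over spots without an outlier mark. For Dahl S against SHR the 4 bars reach 2605, 4345, 866 and 601.

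In 132 probes Dahl S differed from both other strains in the same direction, 59 higher and 73 lower, 25 of them noncoding; 10 more differed in opposite directions. Havcr1, Nfil3 and Dcn were higher in Dahl S than in both, and Hsd3b2 and Mx2 lower, with Hsd3b2 against SHR turning to 0.17 under normexp. Independent lists of the same sizes would share 8.28 probes upward and 10 downward, and 50 simulations with no effect, in which almost no probe can pass, shared 0 on average. The 2 sets of differences correlated with r = 0.507 across probes, against 0.491 in simulation, and their covariance was 0.191 against 0.0757. Without SHR replicate 3, 421 probes overlapped. Leaving out Dahl S replicates 1, 2 and 3 gave 72, 45 and 48, leaving out Dahl R replicates 1, 2 and 3 gave 55, 46 and 52, and the version coded first 22. Both hypertensive strains differed from Dahl R in the same direction in 105 probes, 54 higher and 51 lower, 20 of them noncoding, and 19 differed in opposite directions. Xdh, Asb3, Resp18 and Nes were higher and Prcp lower in both. Dahl R was the only strain they were set against, so such probes cannot be told from ones particular to Dahl R. Independent lists would share 8.84 and 6.37, simulations shared 0, and r was 0.124 against 0.498, with a covariance of 0.0405 against 0.0772. Without SHR replicate 3, 314 overlapped. Leaving out the Dahl S replicates in the same order gave 62, 41 and 42, the Dahl R replicates 43, 35 and 41, and the version coded first 16. Both overlaps share arrays between their comparisons, so part of the excess may come from those arrays. The simulated covariances, 0.0757 and 0.0772, were nearly equal, so the simulated noise was much the same in Dahl S and Dahl R. The real arrays were not: r was 0.995 to 0.997 within Dahl R, and 0.973 and 0.974 for Dahl S replicate 1 with its strain. The simulated r and covariance are therefore no fair reference for either overlap.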

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

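The main scaling, a percentile over all spots, replaced the version coded first after the counts of that version were seen. That version and the percentile over spots without an outlier mark were then added as alternatives, and the other alternatives were planned. Results are given in the order Dahl S against Dahl R, Dahl S against SHR, SHR against Dahl R, with overlap A for probes differing in Dahl S from both other strains and overlap B for probes differing in both hypertensive strains from Dahl R. The main values were 233, 2605 and 2165 probes, 41, 724 and 552 noncoding, overlaps of 132 and 105, and 6, 8 and 4 shifted lists. Among named genes, 3, 3 and 1 values reversed direction, counted only where the gene passed in the main fit or the alternative. Turned signs of genes passing in neither were not counted. In 355, 705 and 610 values a gene past the threshold in the main fit no longer passed. Keeping outlier spots, an intensity trend with a robust prior, and a filter requiring all 3 arrays of at least 1 strain left the probe counts and overlaps nearer the main values, at 215, 308 and 272 probes for Dahl S against Dahl R; lists were not tested there. Array weights raised the probe counts and overlaps most, other scalings lowered them, and leaving out SHR replicate 3 raised them. The cause was not tested beyond the closing observations.

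Counts of probes were 57, 953 and 736 with quantile normalization, 67, 953 and 789 with median centring, 43, 550 and 416 with normexp, 93, 1491 and 1188 with no filter on dim probes, 746, 1076 and 1138 when only the 2 strains compared were fitted, 2313, 6127 and 5340 with array weights, and 153, 1157 and 912 at 2-fold or more. They were 40, 626 and 503 with the percentile over spots without a mark, and 38, 601 and 477 in the version coded first. The slide block gave 866 for Dahl S against SHR.

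Noncoding counts were 16, 317 and 214 with quantile normalization, 16, 258 and 193 with median centring, 9, 125 and 94 with normexp, 20, 435 and 326 with no filter, 166, 295 and 314 with only 2 strains, 538, 1752 and 1480 with array weights, 11, 176 and 131 with the percentile over spots without a mark, and 9, 159 and 127 in the version coded first. For Dahl S against SHR they were 431 with the filter on all 9 arrays, 255 with the slide block and 366 at 2-fold or more, and for SHR against Dahl R 267 at 2-fold or more. The share higher among noncoding probes was 43.1% in Dahl S against SHR, 59.6% with quantile normalization and 72% with normexp; in SHR against Dahl R it was 56.9%, 43.9% and 42.6%, and in Dahl S against Dahl R 39%, or 66.7% with normexp.

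Overlaps A and B were 27 and 30 with quantile normalization, 36 and 28 with median centring, 21 and 19 with normexp, 50 and 42 with no filter, 1255 and 723 with array weights, 81 and 53 at 2-fold or more, 24 and 17 with the percentile over spots without a mark, and 22 and 16 in the version coded first; the slide block gave 72 for A. Shifted lists for Dahl S against SHR numbered 5 with normexp, 4 with the slide block and 5 with the authors' values. An estimated correlation gave 0, 0 and 0 lists, and fry gave 3 for Dahl S against Dahl R and 11 for SHR against Dahl R.

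Leaving out 1 array gave 74 (Dahl R replicate 2) to 761, 1280 (Dahl S replicate 2) to 4345 and 960 (Dahl R replicate 2) to 3772 probes, the highest each without SHR replicate 3. Noncoding counts ran from 16 to 155, 372 to 1283 and 255 to 1059, and overlaps from 45 to 421 for A and 35 to 314 for B. Shifted lists ran from 5 to 9, 6 to 9 and 4 to 7.

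Of the called named genes, 14 of 46, 61 of 128 and 52 of 113 were still called with normexp, 25, 75 and 67 with quantile normalization, and 34, 106 and 97 with the authors' values. Reversed under normexp were Mybphl (0.78), Tacr3 (0.16) and uc.95- (0.72) in Dahl S against Dahl R, and Ppara (0.32), Krt20 (0.35) and Hsd3b2 (0.17) in Dahl S against SHR. Wnk4, at -0.02 in SHR against Dahl R, ran from -0.36 without SHR replicate 1 to 0.50 without SHR replicate 3, a reversal. Averaging all probes of a gene kept 1 of 3 called genes with several probes in Dahl S against SHR and 0 of 2 in SHR against Dahl R.

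A block for the replicate number gave 75 probes for Dahl S against Dahl R, 17 of them noncoding, 1424 for SHR against Dahl R, and overlaps of 46 and 38. Deviations from the strain mean correlated with r of -0.16 to 0.06 between arrays with the same number, so no pairing by number was seen. Arrays with different numbers were not set beside these values, so they cannot exclude such a pairing.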

Other observations

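The tests of a raised background and of bright spots lost to outlier marks, and the narrower form of the shared symbol root, were written after the values were seen; the other tests were planned. Clock genes moved both ways between Dahl S and SHR, with 4 of 15 higher in Dahl S, 6 lower and 5 not passing (camera adjusted p = 0.631 for the list). Nfil3 was 3.92-fold and Bmal1 2.53-fold higher, and Dbp 4.05-fold and Per3 3.71-fold lower (adjusted p = 0.000199 for Nfil3). The labels give no hour of tissue collection. Major histocompatibility genes went both ways: in SHR against Dahl R 10 of 34 were higher, 5 lower and 19 not passing (camera adjusted p = 0.0894), with RT1-CE15 7.56-fold higher on 2 usable SHR arrays and RT1-O1 4.74-fold lower. Named noncoding genes lower in Dahl S than in SHR included H19 (4.12-fold, adjusted p = 0.0142) and Terc, the telomerase RNA (2.74-fold, adjusted p = 0.0272).

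SHR replicate 3 stood apart from the other 2 SHR arrays. Its median position between Dahl R (0) and SHR replicates 1 and 2 (1) was 0.902, and the same between Dahl S and those arrays, which excludes a Dahl R or Dahl S sample under that label; other strains were not tested. The deviation from those arrays was 1.77 in the dimmest 10% of probes and 0.35 in the brightest, a difference of 1.42, so a raised background on that array may explain the lifted dim probes. Keeping the spots marked as outliers gave 2380 probes for Dahl S against SHR, against 4345 without the array. The signals put back may themselves be faulty, so this cannot decide whether the loss of bright spots lowered the counts.

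Strain and slide overlap, so slide was weighed as a source of the differences. On a scale from the other Dahl R arrays (0) to Dahl S (1), Dahl R replicate 1, which lay on the Dahl S slide, had a median position of 0.0361 over 88 probes. On a scale from Dahl R replicate 1 (0) to SHR replicates 1 and 2 (1), the Dahl R arrays on the SHR slide had a position of 0.081 over 1140 probes. Over these probes the Dahl R arrays thus lay near each other on either slide. Both values rest on 1 array, Dahl R replicate 1, so slide is not excluded as a source. Dahl S and SHR, which share no slide, had no such test. There 866 probes passed with slide as a block, against 2605 without it.

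Called genes lay beside each other on the chromosomes more often than in most of 10000 shuffles. The share whose next measured gene was also called was 6.7%, 18% and 15.8% for Dahl S against Dahl R, Dahl S against SHR and SHR against Dahl R, reached by 1, 29 and 58 shuffles. These shares lie above 95% of the shuffles, the bound set in advance against chance placement. They also lie within the full range of the shuffles, the outcome set in advance for chance placement. The outcomes set in advance overlap, so the test cannot exclude chance placement. With pairs sharing a symbol root left out, the shares were 3.35%, 15.3% and 12.9%, reached by 558, 2195 and 4611 shuffles, and a narrower root gave 3.35%, 15.7% and 13.4%. Neighbouring genes of the same family, whose probes could also respond to each other's transcripts, may therefore account for the excess.

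Splits of the 6 arrays of a comparison into 3 and 3 number 10, too few for a share under 0.05. For probes, only the real split reached the real count (1 of 10 in each comparison), with 233, 2605 and 2165 probes against 0, 2 and 0 in the highest other split, and 41, 724 and 552 noncoding against 0, 1 and 0. For shifted lists, 6, 2 and 6 of 10 splits reached the real 6, 8 and 4, and the highest other splits gave 8, 9 and 8. Of 100 splits of all 9 arrays into groups of 3, 3 reached the 132 probes in which Dahl S differs from both other strains and 4 the 105 in which both hypertensive strains differ from Dahl R. The highest other split gave 1573 in each and kept the strains, with SHR as the strain singled out. The others kept the 3 SHR arrays together as that group and mixed Dahl S with Dahl R, with 1178 probes for the former count and 1204 and 1210 for the latter.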
